A study of Mus musculus with 2 samples.

How the data were processed

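The series compares immune cells from the livers of BALB/c mice that carried liver metastases of CT26, a mouse colon carcinoma line, after injection of the tumour cells into the spleen. Per the labels, 1 library came from mice given the vehicle (10% Cremophor) and 1 from mice given F5446 at 10 mg/kg in that vehicle, in 5 doses every 2 days, the first on day 4. F5446 is known as an inhibitor of SUV39H1, a methyltransferase that places H3K9me3. The title of the control sample says untreated while its treatment label says 10% Cremophor, and the treatment label is followed here. The number of mice behind each library is not given in the sources used here. Cells were enriched with beads for CD45 (the product of Ptprc), so the shares of cells without CD45 follow the selection as well as the tissue.

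The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode. Libraries were made with the 10x Chromium 3' v3.1 chemistry per the labels, and aligned with Cell Ranger to mm10 per the submitters' processing notes, which give no version. The deposited gene list holds 33696 genes. Of their gene IDs, 32012 are in GENCODE release M21 (GRCm38) and 1684 are not, and several symbols (Skic3, H2ac24, Septin3) are newer than that release. Symbols are therefore used as deposited.

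Before the data were examined, the cell filters, the marker genes of 27 cell classes, 29 gene lists, the rule for naming genes and 15 alternative settings were fixed. Barcodes with at least 300 detected genes and at most 10% mitochondrial UMIs were kept, and Scrublet was run per library to remove doublets. The alternative called no cell filter drops both limits but still leaves out called doublets. Scrublet called 2.78% of vehicle and 6.39% of F5446 barcodes, against 15.6% and 16.7% expected from the loading, so doublets remain in both libraries. The cells of both libraries were clustered together on 2000 variable genes without mitochondrial genes and receptor variable segments, with 30 principal components, 15 neighbours and Leiden resolution 1.0, and T or NK clusters were clustered again.

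Clusters were named from mean marker scores. A name needed a score of at least 0.75 and 3 markers detected in at least 10% of cells. A cluster scoring for a second lineage (at least 0.5 and at least 0.45 of the first score) was set aside as mixed lineage. T and NK sub-clusters had no minimum score. They were named where a marker of the subset, such as Cd8b1, Cd4, Foxp3 or Ncr1, reached 0.3 of its highest sub-cluster level. Those with at least 2 leading genes of other lineages were set aside as mixed lineage. Unnamed clusters with less than 0.2 of the mean Ptprc level are called Ptprc-low. The naming rule went through 4 versions after the clusters and the number of cells per class and library had been seen, while the marker genes stayed as fixed, and its first version is kept as an alternative. Names mean resemblance only, as in CD8 T-like, and the class with stellate cell or fibroblast markers is called fibroblast-like.

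Only 1 library stands in each group, so no test between groups was possible, and no p-value, standard error or count of changed genes was made from cells. Shares of kept cells carry exact Clopper-Pearson 95% intervals. Gene ratios are F5446 over vehicle from UMIs summed per class and library, scaled to the total of the class (CPM), as log2 with a prior of 0.5 UMI, and their intervals come from the exact binomial split of the UMIs. All intervals cover counting error only, not differences between mice. Those of ratios and list medians treat every UMI as independent, so they are too narrow where UMIs gather in few cells. A gene with 0 UMIs in a library is given as "at least N-fold", taking 3 UMIs over the class as the most that 0 leaves open.

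A class was compared with at least 100 cells in each library. In the main processing these were the CD8 T-like, macrophage-like, Kupffer-like, monocyte-like, fibroblast-like and Ptprc-low cells. List medians use members with at least 20 UMIs, have intervals from 1000 Poisson draws of the counts, and are placed as a percentile among 10000 random lists matched in 20 expression bins. That percentile is a description of these libraries. Named genes are the 10 with the highest and the 10 with the lowest ratio in CD8 T-like and macrophage-like cells and 5 of each elsewhere. They needed at least 100 UMIs in the higher library and at least 0.5 of that library's CPM over all cells. Every member of the cytotoxic list and the pair of members furthest from 0 in every other list are named as well. Shares of cells with a UMI were read after 1 random thinning of every cell to 1000 UMIs. Values of a few single genes are not reported here.

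The alternatives with limits of 20% and 30% mitochondrial UMIs, without the mixed-lineage rule and with the first naming rule were chosen after seeing the data. So were those without 1 macrophage-like cluster, with CD8 T-like sub-clusters given the same weights in both libraries and with each cluster alone. The same holds for the count of Ptprc-low clusters with a median of at least 10000 UMIs. The comparison of further classes at the 30% limit was chosen then too. The 6 lists and 3 gene shares given most weight in the text were picked after their values were seen. The genes of the regulatory T list gave no value, since that class had under 100 cells.

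The ratios were tested on simulated data made from the CD8 T-like and macrophage-like sums over 33696 genes, of which 200 were changed. The counts were drawn gene by gene from Poisson distributions, the model the intervals rest on, so the rates below hold for it alone. UMIs gathered in few cells and genes that vary together were not simulated. A planted 1.5-fold difference gave an interval without 1 for 90.6% of the genes set higher and 84.2% of those set lower in the CD8 T-like sums, and for 84.4% and 81.6% in the macrophage-like sums. At 2-fold these shares were 96.7% and 94.4%, and 100% for both in the macrophage-like sums. Of unchanged genes, 4.42% and 4.22% had such an interval. Unchanged lists of 15 genes fell outside the central 95% of random lists in 3 and 2 of 100 draws, and a list planted at log2 0.263 gave 0.26 and 0.19, each at percentile 100. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and igraph 0.11.9 were used.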

Results

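Among kept cells, the shares of Kupffer-like, macrophage-like and monocyte-like cells were lower and those of Ptprc-low and fibroblast-like cells higher in the F5446 library. CD8 T-like cells made up 8.04% (7.32 to 8.80) of 5288 vehicle and 7.10% (6.18 to 8.12) of 2773 F5446 cells, a ratio of 0.884 with intervals that overlap. Monocyte-like cells, 11.4% and 5.95%, were 0.522 of the vehicle share. Kupffer-like cells (resident liver macrophages) were at 19.0% and 14.5%, and macrophage-like cells at 20.2% and 17.5%, ratios of 0.760 and 0.867. Ptprc-low cells were at 13.9% and 26.8%, 1.93 times the vehicle share, and fibroblast-like cells at 2.42% and 5.16%, 2.13 times. Not every immune class was lower: immature neutrophil-like cells were at 1.15% and 2.60%. The total here is all kept cells, so the higher Ptprc-low share by itself lowers the others. With Ptprc-low, fibroblast-like, endothelial-like and erythroid-like cells left out of the total, the CD8 T-like and macrophage-like shares were higher in the F5446 library. The Kupffer-like and monocyte-like shares stayed lower. These shares follow CD45 bead selection, removal of called doublets and the 10% mitochondrial limit, which keeps 27.2% of vehicle and 13.3% of F5446 barcodes once doublets are removed. With a 30% limit the ratios were 1.19 for CD8 T-like, 1.13 for monocyte-like, 1.22 for macrophage-like, 0.876 for Kupffer-like, 1.204 for fibroblast-like and 0.831 for Ptprc-low cells, a class whose part with few UMIs is then 901 vehicle and 362 F5446 cells, against 95 and 42 at the 10% limit. Its part with many UMIs was at 5.61% and 7.20% with the 30% limit. Mixed-lineage clusters held 8.28% and 8.51% of kept cells, and unnamed T or NK clusters 1.30% and 0.577%. The mixed-lineage cells include clusters led by B cell markers (107 and 48 cells, and 120 and 76). They also include T sub-clusters scoring highest for CD4 T (such as 93 and 58 cells, and 56 and 13). Without the mixed-lineage rule 246 vehicle and 142 F5446 cells were called B-like.

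**Figure D1:**
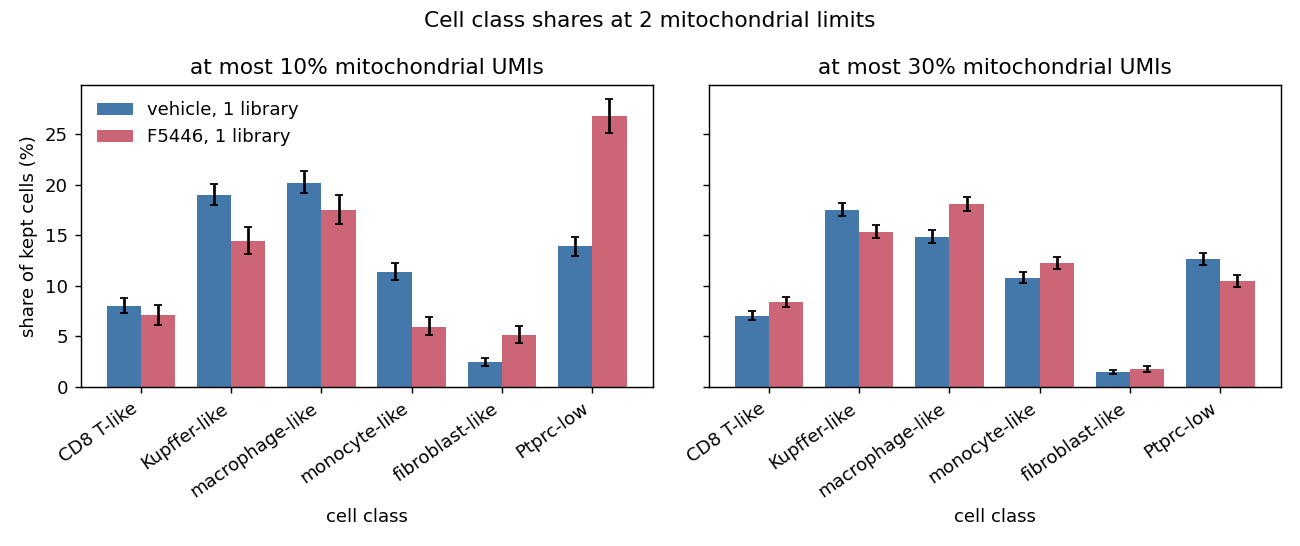
Share of kept cells in percent (vertical axis) of the compared classes in the vehicle and F5446 libraries, with at most 10% mitochondrial UMIs on the left and at most 30% on the right; each bar is 1 library and error bars are exact 95% intervals of counting error. The Ptprc-low share is 13.9% and 26.8% at the 10% limit. Its order turns at the 30% limit, where cells with few UMIs make up a larger part of the class.

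CD8 T-like cells of the F5446 library carried less RNA of several cytotoxic effector genes. Gzma, a granzyme protease released into target cells, had a log2 ratio of -1.11 (7705 vehicle and 1669 F5446 UMIs), and Ccl5, a chemokine for T cells and monocytes, -0.71. Fasl, the death receptor ligand, was at -0.50, Gzmk (another granzyme) at -0.41, the lectin receptor gene Klrd1 at -0.38, the cytokine gene Ifng at -0.30, the granule protease gene Ctsw at -0.28, perforin (Prf1) at -0.25 and the granule membrane gene Nkg7 at -0.24. Closer to 0 were the cytokine gene Tnf (-0.15), the granzyme inhibitor gene Serpinb9 (-0.12), Gzmb (-0.11), the lysosome membrane gene Lamp1 (-0.09) and the protease inhibitor gene Cst7 (-0.04). Members with higher values in the F5446 library were the chemokine genes Xcl1 (0.62), Ccl3 (0.36) and Ccl4 (0.34), and Tnfsf10 (0.11), which encodes the death ligand TRAIL. Gzmm (8 and 2 UMIs) and Klrg1 (11 and 5) had too few UMIs to enter. The list median over 18 members was -0.19 (-0.28 to -0.12), at percentile 0 of random lists, with 1 member at least 1.5-fold higher, 2 lower and 15 between. The 4 sub-clusters behind the class held 121, 75, 150 and 79 vehicle and 82, 32, 66 and 17 F5446 cells. The median was -0.08 with the 20% limit, -0.12 with the 30% limit (Gzma -0.16, Ccl5 0.15) and -0.03 without any cell filter (Gzma 0.17, Ccl5 0.30). The last of these settings called 506 vehicle and 505 F5446 cells CD8 T-like, against 904 and 924 at the 30% limit. With each library clustered alone Xcl1 turned to -0.90 and Gzmk to 0.12, and thinning turned Fasl to 0.51. No test was possible with 1 library per group.

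**Figure D2:**
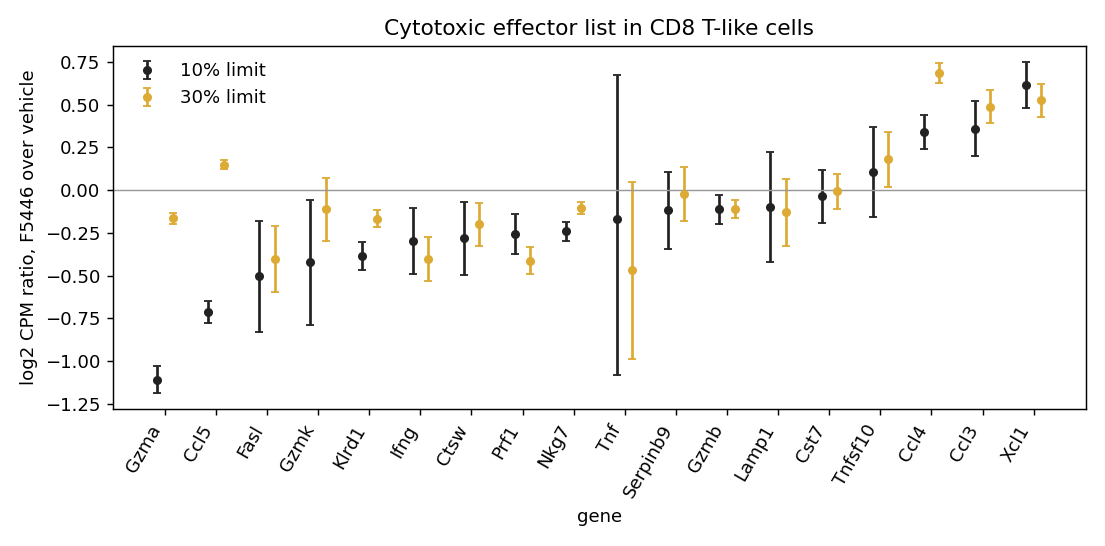
Log2 CPM ratio, F5446 over vehicle (vertical axis), of each cytotoxic effector gene in CD8 T-like cells at the 10% and 30% mitochondrial limits; points come from UMIs summed over the class with 1 library per group, and error bars are exact 95% intervals of counting error. Gzma lies lowest at -1.11 and Xcl1 highest at 0.62 at the 10% limit.

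The shares of CD8 T-like cells with a UMI of Gzmb, Prf1, Ifng and Gzma had overlapping intervals in both libraries once every cell was thinned to 1000 UMIs. Gzmb was found in 36.6% (32.0 to 41.3) of vehicle and 36.0% (29.3 to 43.2) of F5446 cells, Prf1 in 28.8% and 24.9%, Ifng in 11.1% and 8.63%, and Gzma in 106 of 424 vehicle cells (20.9% to 29.4%) and 35 of 197 F5446 cells (12.7% to 23.8%). Fasl was at 5.19% and 7.11%, Gzmk at 4.72% and 5.58%, Cd69 (an early activation marker) at 4.48% and 3.55%, and Tnf at 0.943% and 0%. Of the inhibitory receptor genes, Pdcd1 (PD-1) was at 20.05% and 15.2%, Lag3 at 9.43% and 8.12%, Havcr2 (TIM-3) at 14.2% and 16.8%, and Tigit at 2.36% and 2.03%. Tox, a transcription factor of exhausted T cells, was at 53.3% (48.4 to 58.1) and 66.0% (58.9 to 72.6), and at 76.8% (72.5 to 80.8) and 82.7% (76.7 to 87.7) with 2000 UMIs per cell. With 1000 UMIs the cell cycle genes Top2a and Mki67 were at 26.4% and 36.5% and at 9.20% and 14.2%. Of the genes of naive and memory cells, the interleukin 7 receptor gene Il7r was at 6.60% and 2.03% (30.6% and 24.4% without thinning), and the transcription factor gene Tcf7 at 0.472% and 0%. Without thinning, at median depths of 10871 and 11006 UMIs, Gzmb was found in 80.0% and 83.2%, Prf1 in 77.2% and 71.6%, Ifng in 52.2% and 49.2%, and Gzma in 33.6% and 31.0%. Kupffer-like cells (median depths 13159 and 13168) gave a background of 0% and 0.249% for Gzmb, 0.497% and 0.748% for Gzma, and 0.398% and 0.748% for Tox after thinning. With 2000 UMIs per cell the order for Ifng turned, to 17.0% and 23.9%. Il7r turned to a higher F5446 share in several alternative settings, and the order for Top2a turned with the 30% limit.

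Outside the lists, the genes furthest below the vehicle level in CD8 T-like cells of the F5446 library included Gzmg, Cd7 and Dapl1. Gzmg, a granzyme, had 190 vehicle UMIs and 0 in the F5446 library, at least 29.6-fold lower, but 96.8% of them came from 5 cells. Gzmd (-1.02; 514 and 118 UMIs) and Gzme (-0.90) are close relatives of Gzmg, and reads can be shared between them. Gzmd and Gzme are also leading genes of a sub-cluster with 79 of 425 vehicle and 17 of 197 F5446 CD8 T-like cells. The lymphocyte surface gene Cd7 was at -1.32 (509 and 95), Dapl1 (known from memory CD8 T cells) at -1.33, AA467197 (the mouse gene for NMES1) at -1.06, Rundc3b (RUN domain) at -1.03, the receptor gene Klra5 at -0.96, the RNA polymerase III subunit gene Polr3c at -0.90 and Serp2 (secretory pathway) at -0.87. Higher were Atrnl1 (attractin-like, 1.003), the centriole gene Cntln (0.86), the scaffold gene Magi3 (0.73), the histone acetyltransferase gene Kat6b (0.71), the DNA repair ligase gene Rad18 (0.70), the RNA-binding gene Myef2 (0.67), the heat shock gene Hsph1 (0.67), the RNA decay gene Skic3 (0.66), the spindle checkpoint gene Mad1l1 (0.65) and Shcbp1 (cell division, 0.65). With Leiden resolution 0.5 the order of Gzmd and Gzme turned, and thinning turned Cntln and Skic3.

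Genes of proliferation and of stress were higher in CD8 T-like cells of the F5446 library by small amounts. The proliferation list had a median of 0.21 (percentile 99.99), with all 19 members between the 1.5-fold limits, Tpx2 (spindle assembly) at 0.46 and Ccnb1 (cyclin B1) at 0.44. The stress and dissociation list was at 0.29 (percentile 99.96, 1 higher, 1 lower, 17 between), with the phosphatase gene Dusp1 at 0.86 and Ier3, an early response gene, at -0.65. Antigen presentation by MHC class I was lower, -0.12 (percentile 0.59, H2-D1 -0.26, H2-Q4 -0.22). The checkpoint and exhaustion list stood at -0.01 (percentile 21.6; 1 of 14 members at least 1.5-fold higher), with the early response factor Nr4a1 at 0.93 and the receptor gene Cd244a at -0.39. The naive and memory list was at 0.06 (percentile 52.95; 3 higher, 1 lower, 8 between; the homing receptor Ccr7 0.96, the transcription factor Klf2 0.95). T cell activation was at 0.09 (percentile 74.2, Il2ra 0.51, Batf 0.32) and effector transcription factors at -0.03 (percentile 17.1, Ikzf2 0.29, Prdm1 -0.24). Helper subset genes over all named T-like cells were at -0.05 (percentile 22.0, 4 members). Of these 458 vehicle and 205 F5446 cells, 425 and 197 were CD8 T-like and the rest regulatory T-like. No CD4 T-like class was named, so the value says little about helper cells. Trafficking receptors were at -0.14 (percentile 1.51), although the chemokine receptor genes Cxcr3 (1.67; 14 and 21 UMIs) and Cxcr4 (1.499) were higher. Interferon-stimulated genes were at 0.10 (percentile 74.6, Mx1 0.92, Rsad2 0.91), interferon-gamma induced genes at -0.10 (percentile 3.32, Cxcl10 0.84, Socs1 -0.77), and apoptosis and p53 genes at 0.02 (percentile 36.5, Bbc3 0.50, Fas 0.42). The median of the proliferation list turned to -0.11 with the 30% limit, and thinning turned that of the stress list. The 20% limit turned Cxcr3, Klf2 and Il2ra, and thinning turned Klf2 and Il2ra.

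In macrophage-like cells Prg4, Alox15 and Serpinb2 had the lowest log2 ratios with the prior, mostly through 1 cluster. Prg4, which encodes the lubricant lubricin, had 1197 vehicle and 5 F5446 UMIs (-6.60), and Alox15, a lipoxygenase, 1420 and 7 (-6.40). Serpinb2, a plasminogen activator inhibitor, was at -5.29, the secreted protease inhibitor Slpi at -3.70 (11090 and 381 UMIs), the cystatin gene Cstdc4 at -3.34, Tgfb2 (a growth factor) at -3.19, the adhesion receptor Selp at -2.55 and Garnl3 (GTPase activating domain) at -2.36. Prok2, a secreted peptide, had 120 and 1 UMIs, a ratio of 0.0187 (0.0005 to 0.106), and Ptgis, the prostacyclin synthase, 199 and 2, a ratio of 0.0225 (0.0027 to 0.0824). Higher in the F5446 library were the monocyte chemokine Ccl8 (1.49; 2858 and 3595 UMIs), the fatty acid carrier Cd36 (1.45), the lipase Lpl (1.31), the carbonyl reductase Cbr2 (1.36) and Ctla2a, a protease inhibitor (1.54). So were Nrgn (neurogranin, 2.02, with 93.0% of F5446 UMIs in 5 cells), Tbc1d4 (glucose transport, 1.04), Banp (DNA binding, 0.90), the growth factor gene Pdgfc (0.86) and the helicase gene Zgrf1 (0.85). A single cluster of 75 vehicle and 63 F5446 cells holds 1192 of the vehicle Prg4 UMIs, in 49 cells. Outside this cluster Prg4 had only 5 and 1 UMIs and Alox15 7 and 2, Slpi was at -0.75 (349 and 91 UMIs) and Ccl8 at -0.07, while Cd36 (1.21) and Lpl (1.30) stayed higher. With each library clustered alone, the cells called macrophage-like differ and Prg4 turned to 1.01, Alox15 to 0.19, Serpinb2 to 0.40, Slpi to 0.53, Selp to 1.32, Garnl3 to 0.66, Prok2 to 2.60 and Ptgis to 0.16. In that setting the class held 12268035 vehicle and 6079881 F5446 UMIs. Equal UMI counts of a gene in both libraries already give a value like that of Prg4. The counts behind these values are not given here, so the turns may rest on few UMIs.

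Among the lists, MHC class II presentation was higher and suppressive genes were lower in macrophage-like cells of the F5446 library. The class II median was 0.27 (0.23 to 0.30; percentile 99.99) with 8 of 8 members between the 1.5-fold limits, and the regulator Ciita at 0.51 and H2-DMb1 (peptide loading) at 0.35. The suppressive and tissue-repair list was at -0.18 (-0.32 to -0.12; percentile 0; 1 higher, 4 lower, 14 between), with Thbs1, a matrix protein, at -0.99 and the cytokine Il10 at 0.95. Proliferation genes were at 0.29 (percentile 100, Mcm5 0.62, Stmn1 0.40), and Kupffer identity and lipid or iron genes at 0.19 (percentile 99.75; 5 higher, 2 lower, 10 between; the scavenger receptor Marco -1.58). Inflammatory genes were at -0.05 (percentile 6.66), with the neutrophil chemokine Cxcl3 at -1.81 and Il1a (interleukin 1) at -0.59. Interferon-stimulated genes stood at 0.06 (percentile 73.8, Ifit1 0.55, Irf7 -0.50), interferon-gamma induced genes at 0.05 (percentile 55.2, Nos2 0.49, Irgm1 0.41), MHC class I at -0.07 (percentile 4.23, Nlrc5 0.34, H2-T23 -0.28), apoptosis genes at -0.13 (percentile 0.46, Trp53inp1 0.37, Bbc3 -0.34) and stress genes at -0.09 (percentile 0.24, Fosb 0.90, Ier3 -0.71). By cluster the class II median ran from 0.93 in the Alox15 and Prg4 cluster through 0.47 and 0.11 to -0.11. The suppressive median in the same order was 0.15, -0.48, -0.06 and 0.00, and only that of -0.48 had an interval without 0. These clusters held 75, 106, 562 and 326 vehicle and 63, 83, 185 and 155 F5446 cells. The medians over the class therefore also carry a different mix of clusters. The proliferation, stress and Kupffer identity medians turned with the 20% and 30% limits, and the class II median was 0.12 after thinning to 1000 UMIs.

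Kupffer-like cells of the F5446 library carried more Ccl8, Cxcl9 and Cxcl2 RNA. Ccl8, a monocyte chemokine, was at 2.31 (437 and 817 UMIs), Cxcl9, a T cell chemokine induced by interferon gamma, at 1.18, and Cxcl2, which attracts neutrophils, at 0.97. Il12b, a subunit of interleukins 12 and 23, had 3 vehicle and 69 F5446 UMIs, a ratio of 61.2 (20.1 to 304). The lectin gene Cd209b was at 5.10 (16 and 212 UMIs), with 98.1% of its F5446 UMIs in 5 cells, and Spata13 (a GTPase regulator) at 0.99. Lower were the mitophagy kinase gene Pink1 (-1.57), the DNA repair nuclease gene Mus81 (-1.43), Phf7 (a chromatin reader, -1.37), the fatty acid transporter gene Slc27a6 (-1.32) and Ptgis (-1.24). The interferon-stimulated list had a median of -0.12 (-0.16 to -0.08; percentile 0.265), with all 19 members between the 1.5-fold limits, Ifi27l2a at -0.44 and Irf7 at -0.40. The interferon-gamma induced list was at 0.21 (percentile 99.98; 2 higher, 11 between), with Socs1, a feedback inhibitor, at 0.60. MHC class I was at -0.12 (percentile 1.07, H2-Q7 -0.50, H2-D1 -0.35) and class II at 0.11 (percentile 96.1, Ciita 0.40, H2-DMb1 0.39). Suppressive genes stood at 0.18 (percentile 99.9; 4 higher, 2 lower, 13 between; Gpnmb -2.47, Thbs1 1.004), and inflammatory genes at 0.06 (percentile 81.0; 3 higher, 2 lower, 9 between). Proliferation was at 0.10 (percentile 97.8, Mcm2 0.66, Mcm5 0.52), stress at 0.07 (percentile 92.6, Fosb 0.49, Dnaja1 0.48), and Kupffer identity at -0.08 (percentile 5.24, Apoc1 -0.56, Fabp5 0.39). The interferon-gamma induced and proliferation medians turned with limits of 20% and 30%, and thinning to 1000 UMIs brought the interferon-stimulated median to -0.0063.

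Monocyte-like cells of the F5446 library had more Cxcl2 and less Il1b RNA. Cxcl2 was at 1.51 (220 and 180 UMIs), Ch25h, which makes 25-hydroxycholesterol, at 1.52, the phosphodiesterase gene Pde4d at 1.39, Ccl8 at 1.21 and Frmd4b (a scaffold) at 1.18. The surface protein genes Ly6a2 (135 and 5 UMIs) and Ly6i were at -2.82 and -1.63, the RNA-binding gene Rbpms at -1.21, the protease inhibitor gene Serpinb10 at -1.14 and the cytokine Il1b at -1.03 (979 and 137). The inflammatory median was 0.29 (-0.11 to 0.40; percentile 99.9; 4 higher, 2 lower, 9 between), an interval that includes 0, and that of suppressive genes was 0.17 (percentile 99.2; 5 higher, 2 lower, 11 between), with Spp1 (osteopontin) at 0.96 and Hmox1 (heme breakdown) at 0.93. Stress genes were lower, -0.22 (percentile 0; 1 lower, 19 between; Nfkbia -0.63, Dusp1 -0.57), as were interferon-stimulated genes, -0.14 (percentile 0.11; 1 lower, 18 between; Ifi27l2a -0.59, Irf7 -0.50), and MHC class I, -0.14 (percentile 0.76, H2-Q4 -0.77, H2-Q7 -0.41). MHC class II was at 0.13 (percentile 96.5, Ciita 0.62, H2-Eb1 0.25), interferon-gamma induced genes at -0.02 (percentile 31.2, Nos2 -0.60, Irf1 -0.46) and proliferation at -0.08 (percentile 7.20, Mcm2 -0.95, Cdk1 -0.54). Ccl8, Spp1 and the stress and suppressive medians turned at the 20% and 30% limits, and Il1b turned to 0.29 with each library clustered alone.

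Interferon-gamma induced genes lay in opposite directions in fibroblast-like and Ptprc-low cells. In fibroblast-like cells 11 of 14 members were at least 1.5-fold higher in the F5446 library and 3 between (median 0.78, 0.70 to 0.98; percentile 100), with the T cell chemokine Cxcl10 at 1.95 and Nos2 at 3 and 19 UMIs, a ratio of 6.35 (1.87 to 33.5). Proliferation genes were higher too, 0.67 (percentile 100; 11 higher, 8 between), with cyclin Ccnb1 at 1.69 and Mki67 at 1.67, as were interferon-stimulated genes at 0.29 (percentile 98.8; 5 higher, 1 lower, 13 between; Mx1 -0.79, Rsad2 0.77), MHC class I at 0.29 (percentile 98.0, H2-T23 0.83, H2-Q7 0.60) and stress genes at 0.22 (percentile 94.0, Btg2 1.505, Fosb 0.99). The genes furthest apart were Serpinb2 with 3 and 237 UMIs, a ratio of 79.3 (26.8 to 387), and Sfrp2, a WNT modulator, with 2 and 142, a ratio of 71.2 (19.4 to 594). The matrix gene Hmcn1 was at 3.42, the lectin gene Clec3b at 3.27 and Slpi at 3.18 (529 and 4788 UMIs). Lower were Ankrd55 (-1.74), the matrix genes Prelp (-1.68), Omd (-1.65) and Col10a1 (-1.48), and Agt, the angiotensin precursor (-1.66). The class is made up differently in the libraries: 1 cluster holds 106 vehicle and 58 F5446 cells, with an interferon-gamma median of -0.04, and another 22 and 85 cells, with 1.24. Their proliferation medians were 0.19 (-0.08 to 0.28) and 0.52 (0.36 to 0.74). Keratin RNA was also higher in the F5446 library (Krt8 42.5 and 96.2 CPM, Krt18 30.9 and 84.5), while Sox9 and Spp1 of the same marker list were lower. The first naming rule gave 0.04 for the interferon-gamma induced list and turned the proliferation (-0.09), interferon-stimulated (-0.11) and MHC class I (-0.07) medians. Cxcl10, Ccnb1 and Mki67 turned as well. That rule needed a score of only 0.5 and gave a fibroblast-like class of 545 vehicle and 605 F5446 cells. It takes in the Ptprc-low clusters with 233 and 279 and with 184 and 183 cells, so these values mix both classes.

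Ptprc-low cells of the F5446 library had less RNA of interferon-gamma induced genes, with a median of -0.40 (-0.45 to -0.31; percentile 0). Of 14 members 2 were at least 1.5-fold lower and 12 between, with Cxcl10 at -0.94 (1533 and 696 UMIs) and Ido1, a tryptophan-degrading enzyme, at -0.74, while Cxcl9 was higher at 0.52 (236 and 294 UMIs). The median was -0.26, -0.31 and -0.24 in the 3 clusters with many UMIs and -0.58 (-1.20 to 0.05; 7 members) in the fourth. Interferon-stimulated genes were at -0.22 (percentile 0; 19 of 19 between; Irf7 -0.52, Ifit3b -0.50), MHC class I at -0.21 (percentile 0, H2-T23 -0.31, Psmb9 -0.28), proliferation at -0.10 (percentile 0, Mki67 -0.32, Ccnb2 -0.19), and stress genes at 0.00 (percentile 44.5, Fosb 0.49, Ier3 -0.42). Ccn2, a matrix-associated growth regulator, was higher at 1.39 (252 and 576 UMIs), with Mgat4e (a glycosyltransferase, 1.43), Car6 (a carbonic anhydrase, 1.40), Catsperd (a calcium channel subunit, 1.36) and the membrane protein gene Dynap (1.19). Lower were the methyltransferase gene Inmt (-1.12), the peroxisome gene Pex26 (-1.04), the zinc finger gene Zfp773 (-0.9999), the clock gene Cry1 (-0.95) and Zc3h6 (-0.92). Median depth in this class was 40254 and 35476.5 UMIs, the highest of the compared classes. The interferon-gamma median was -0.26 after thinning and -0.27 with each library clustered alone. Inmt turned with each library clustered alone (0.53), Inmt and Ido1 with the first naming rule, and Ido1 (1.21), Mki67 (0.41), Fosb (-0.30) and Catsperd with thinning.

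**Figure D3:**
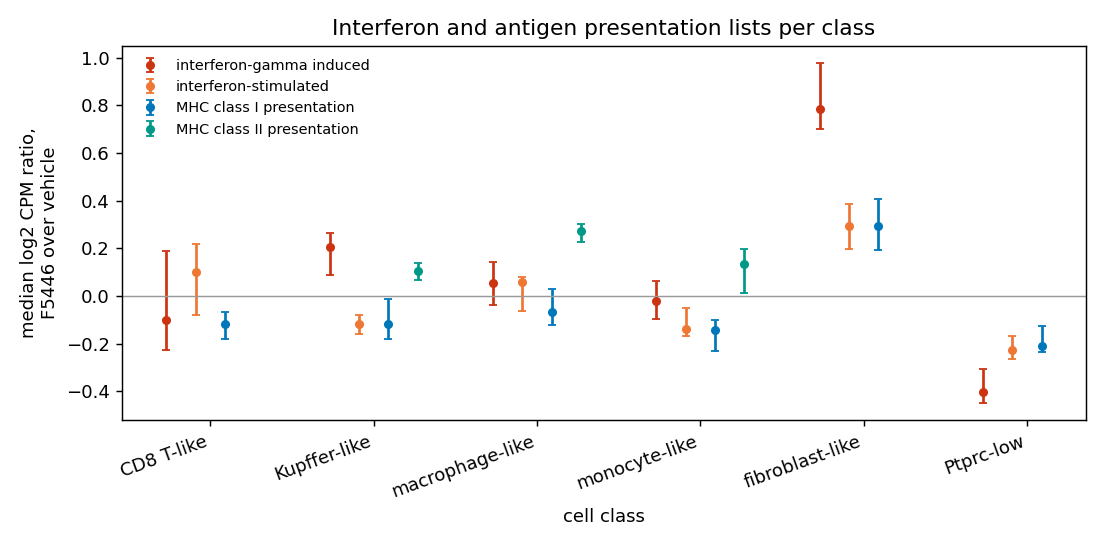
Median log2 CPM ratio, F5446 over vehicle (vertical axis), of 4 interferon and antigen presentation lists in the compared classes with 1 library per group; points are medians over list members and error bars are 95% intervals from Poisson draws of the counts. The interferon-gamma induced list is at 0.78 in fibroblast-like and -0.40 in Ptprc-low cells.

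Genes linked to H3K9 methylation, the step that F5446 targets, were slightly higher in macrophage-like and Kupffer-like cells of the F5446 library. The list holds more than genes that place the mark. Kdm3a, Kdm4a, Kdm4b and Kdm4c remove it, and Dnmt1 and Uhrf1 take part in DNA methylation. Suv39h1 itself was at 23.3 and 26.0 CPM in CD8 T-like cells, a ratio of 1.12 (0.805 to 1.53), and its ratio was 1.54 (1.16 to 2.03) in macrophage-like, 1.10 (0.804 to 1.49) in Kupffer-like, 1.09 (0.501 to 2.20) in monocyte-like, 0.722 (0.471 to 1.10) in fibroblast-like and 0.918 (0.836 to 1.01) in Ptprc-low cells. An inhibitor of the enzyme need not move its RNA. The H3K9 machinery list was at 0.15 (percentile 92.7, Tasor 0.43, Setdb2 0.34) in CD8 T-like, 0.16 (percentile 98.6, Suv39h1 0.62, Suv39h2 0.55) in macrophage-like, 0.15 (percentile 99.9, Uhrf1 0.84, Suv39h2 0.48) in Kupffer-like, 0.10 (percentile 70.5, Kdm3a 0.73, Kdm4a 0.57) in monocyte-like, -0.04 (percentile 14.3, Kdm4a 0.71, Kdm4b -0.63) in fibroblast-like and 0.02 (percentile 61.4, Suv39h1 -0.12, Kdm3a 0.12) in Ptprc-low cells. Zinc finger (Zfp) genes, many of which are silenced by H3K9 methylation, were at 0.07 in CD8 T-like cells (percentile 78.7; 17 higher, 15 lower, 191 between; Zfp235 -1.52, Zfp248 -1.32), 0.05 in macrophage-like (percentile 90.0, Zfp94 1.83, Zfp366 1.69), -0.02 in Kupffer-like (percentile 10.8, Zfp420 -1.82, Zfp382 1.81) and 0.10 in monocyte-like cells (percentile 89.9, Zfp930 1.34, Zfp748 1.34). In fibroblast-like cells their median was -0.10 (percentile 0; 25 higher, 38 lower, 210 between; Zfp791 2.86), where Zfp521 had 1 and 23 UMIs, a ratio of 23.1 (3.75 to 951), and in Ptprc-low cells -0.02 (percentile 57.5, Zfp455 -1.47, Zfp940 -1.23). In macrophage-like cells the Suv39h1 ratio was 1.07 (0.866 to 1.31) with the 30% limit, and without any cell filter both it and the list median turned.

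Mitochondrially encoded RNA was higher in the F5446 library in 5 of the 6 compared classes, and hemoglobin RNA was lower in all 6 at the 10% limit. The mitochondrial list stood at 0.23 in CD8 T-like (mt-Nd6 0.59, mt-Nd4 0.34), 0.26 in macrophage-like (mt-Nd6 0.48, mt-Nd4l 0.38), 0.20 in Kupffer-like (mt-Nd6 0.57, mt-Nd4l 0.30), 0.14 in monocyte-like (mt-Nd6 0.24, mt-Nd4l 0.22), 0.03 (-0.02 to 0.04) in fibroblast-like (mt-Nd6 0.50, mt-Co2 -0.14) and 0.20 in Ptprc-low cells (mt-Nd6 0.63, mt-Nd4l 0.30). The hemoglobin list (4 genes), RNA known to leak from lysed red cells, was at -1.197 in CD8 T-like (Hba-a1 -1.71, Hba-a2 -1.45), -0.77 in macrophage-like (Hbb-bt -2.09, Hba-a2 -0.81), -3.10 in Kupffer-like (Hbb-bs -3.68, Hbb-bt -3.16), -2.11 in monocyte-like (Hba-a2 49 and 1 UMIs, Hba-a1 -2.55), -2.99 in fibroblast-like (Hbb-bs -3.72, Hba-a1 -3.00) and -1.62 in Ptprc-low cells (Hba-a1 -1.73, Hba-a2 -1.62). The hemoglobin median turned in macrophage-like cells, to 0.82 without the Alox15 and Prg4 cluster and to 2.99 with each library clustered alone, and in Ptprc-low cells, to 0.55 with the 30% limit. Hbb-bs was at 2913 and 876 CPM over whole libraries. Hepatocyte RNA was at 0.16 in CD8 T-like (Serpina1a 0.70, Serpina1c 0.70), -0.05 in macrophage-like (Mup3 -1.24, Ttr 0.55), -0.04 in Kupffer-like (Fabp1 -0.51, Apoa2 -0.40), -0.23 in monocyte-like (Fgb -0.56, Apoa2 -0.56), 0.00 in fibroblast-like (Ttr 0.89, Alb 0.70) and 0.32 in Ptprc-low cells (Ttr 0.62, Mup3 -1.11), where it turned to -0.28 with each cell weighted equally and -0.22 with the 30% limit, as did Ttr in both settings. Ribosomal protein genes were at -0.04 (Rpl39l 1.07, Rpl17 -0.19), -0.10 (Rpl39l -0.61, Rpl3l -0.55), -0.07 (Rpl3l 1.41, Rpl39l 0.55), -0.03 (Rpl39l -1.05, Rpl3l -0.44), -0.25 (Rpl39l -0.93, Rpl21 -0.51) and -0.02 (Rpl39 -0.15, Rpl7l1 0.15) in the same order of classes.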

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

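The tests of the mitochondrial limit on the shares, of Ptprc RNA, of Cdkn2a and of keratins against macrophage-like cells were chosen after results were seen, while those of the cytotoxic list and of keratins against fibroblast-like cells were written before their values were seen. The mitochondrial limit alone leaves out 68.9% of vehicle and 74.9% of F5446 barcodes with at least 300 genes, counted over all barcodes, so most barcodes stand outside the main comparison. The kept cells hold 92123952 of 154579861 vehicle and 56950763 of 141085161 F5446 UMIs. Median mitochondrial shares over all barcodes were 17.5% and 24.1%.

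Among all kept cells, the shares of macrophage-like, Kupffer-like and monocyte-like cells, and by a small margin CD8 T-like cells, were lower in the F5446 library. That of Ptprc-low cells was higher. With Ptprc-low, fibroblast-like, endothelial-like and erythroid-like cells left out of the total, the CD8 T-like and macrophage-like shares were higher in the F5446 library. The Kupffer-like and monocyte-like shares stayed lower. The sum of the 4 immune classes over the Ptprc-low class, F5446 over vehicle, was 0.399 at the 10% limit, 0.873 at 20%, 1.30 (1.19 to 1.41) at 30% and 1.14 with no filter. The part of the Ptprc-low class with few UMIs is 95 and 42 cells at the 10% limit and 901 and 362 at the 30% limit, and against the part with many UMIs alone (720 and 793 cells at 30%) the ratio was 0.838 (0.753 to 0.933), compared with 0.368 at the 10% limit. The ratio thus depends strongly on the limit but stays under 1 in this count, so whether the 10% limit together with more mitochondrial RNA per barcode accounts for the shares stays open. With 1 library per group, that limit and F5446 treatment cannot be told apart.

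The cytotoxic list was lower in CD8 T-like cells of the F5446 library, at -0.19. With each sub-cluster given the same weight in both libraries, its part of the summed UMIs, it was -0.14 (-0.22 to -0.05). This met the margin set beforehand against the mix of sub-clusters as the whole cause. Within sub-clusters the medians were -0.26, 0.01, -0.04 and -0.26. With the 30% limit the median was -0.12 (-0.17 to -0.08), past the margin set beforehand. It was -0.08 with the 20% limit and -0.03 without any cell filter, both short of that margin. The part played by the limit therefore stays open, and these 2 settings were weighed only after their values were seen. Without any cell filter 506 vehicle and 505 F5446 cells were called CD8 T-like, against 904 and 924 at the 30% limit. That value thus also reflects which cells were given the name. The limit and F5446 treatment cannot be told apart with 1 library per group.

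Ptprc-low cells with many UMIs were found in both CD45-selected libraries. Their Ptprc level was 0.0494 of that in macrophage-like cells in the vehicle and 0.0405 in the F5446 library. The class was named for less than 0.2 of the mean Ptprc level, so a low value was fixed by the naming rule. It therefore cannot decide whether these cells are pairs of an immune cell and another cell. Keratin markers gave a median log2 ratio to fibroblast-like cells of -0.64 in the vehicle and -1.97 in the F5446 library, but that class holds keratin RNA itself (Krt8 42.5 and 96.2 CPM), and against macrophage-like cells the medians were 0.00 and 0.15 (Krt18 19.4 and 20.9 CPM against 2.15 and 2.75), so the keratins decide nothing. Cdkn2a, a gene that CT26 is known to lack, had 25 of 60984366 UMIs in this class, 0.0499 of the fibroblast-like level. Tumour cells of that line could give such a value. Macrophage-like cells were low too, at 3.56 CPM against 8.22 in fibroblast-like and 0.41 in Ptprc-low cells. What these cells are stays open.

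Interferon-gamma induced genes had a median of 0.78 in fibroblast-like and -0.40 in Ptprc-low cells. This pair was chosen after the values were seen, and the difference between the classes was not tested. In the fibroblast-like cluster with 106 and 58 cells the median was -0.04, and the cluster with 1.24 holds 22 and 85 cells. The fibroblast-like value thus depends on which cells make up the class. The first naming rule gave 0.04, but it calls the Ptprc-low clusters with 233 and 279 and with 184 and 183 cells fibroblast-like. That value therefore pools cells of both classes contrasted here.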

How the results depend on the processing

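No tests between groups were made. The settings with 20% and 30% mitochondrial limits, the first naming rule and no mixed-lineage rule were chosen after results were seen. So were the left-out macrophage-like cluster and the sub-clusters with the same weights in both libraries. Class shares gave 63 values for 6 results, of which 35 stayed within the interval of the main value, 21 moved outside it and 7 turned direction. List medians gave 1285 values for 86 results, of which 992 stayed within the interval of the main value, 262 moved outside it and 31 turned direction. Named genes gave 3448 values for 261 results, of which 2777 stayed within the interval of the main value, 580 moved outside it and 91 turned direction. Shares of CD8 T-like cells with a UMI gave 198 values for 18 results, of which 170 stayed within the interval of the main value, 21 moved outside it and 7 turned direction. A turn is counted only where the main interval excludes no difference, and for a list also where the median lies outside the central random lists. Without the mixed-lineage rule all values stayed within (371 of 371), which says little because that rule leaves nearly all cells of the compared classes as they were. Values otherwise stayed within their interval most often with classes made per cell from markers (5 of 5, shares only), with list members of at least 100 UMIs (82 of 82) or at least 1 UMI (85 of 86), a prior of 5 UMIs (338 of 347) and median-ratio scaling (332 of 347). They moved most with the 20% limit (228 of 371 within), the 30% limit (219 of 371), no cell filter (182 of 328) and thinning to 1000 UMIs (150 of 339). At least 500 genes with at most 5% mitochondrial UMIs gave no value for classes left with under 100 cells in a library, classes made per cell from markers gave shares only, and each library clustered alone or no cell filter gave none for some classes. No paired analysis was possible because each group has 1 library and both carry the same replicate number. Depth limits the rarer genes: under 20 UMIs a gene did not enter a list, thinning to 1000 UMIs leaves few UMIs for most genes, and intervals widen in the classes with fewest cells. For the values that follow, the cause was not tested.

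With at least 500 genes and at most 5% mitochondrial UMIs, share ratios were 0.137 (CD8 T-like), 0.281 (macrophage-like) and 4.51 (fibroblast-like). Interferon-gamma induced -0.46 in Ptprc-low cells was the list median.

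With the libraries clustered alone, share ratios were 0.604 (CD8 T-like), 1.51 (Ptprc-low), 0.848 (monocyte-like) and 1.57 (fibroblast-like). Hemoglobin 2.99 in macrophage-like cells, and interferon-gamma induced -0.27 in Ptprc-low cells were the list medians. The macrophage-like class held 12268035 vehicle and 6079881 F5446 UMIs there, so a gene with equal UMI counts has a positive log2 ratio. Il1b 0.29 and H2-Q7 0.0636 in monocyte-like cells, and Nrgn -0.0471, Prg4 1.01, Alox15 0.19, Serpinb2 0.40, Prok2 2.60, Ptgis 0.16, Slpi 0.53, Selp 1.32, Garnl3 0.66, Rpl39l 0.0172, Hbb-bt 2.89 and Hba-a2 2.9983 in macrophage-like cells, and Inmt 0.53 and Rpl7l1 -0.0166 in Ptprc-low cells, and Gzmb 0.0228, Gzmk 0.12 and Xcl1 -0.90 in CD8 T-like cells were the log2 gene ratios.

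With the 20% mitochondrial limit, share ratios were 1.07 (CD8 T-like), 1.18 (macrophage-like), 0.917 (Kupffer-like), 1.202 (Ptprc-low), 1.05 (monocyte-like) and 1.35 (fibroblast-like). Cytotoxic effector -0.083 in CD8 T-like cells, and MHC class II 0.38, proliferation -0.0168, stress 0.0652 and Kupffer identity -0.12 in macrophage-like cells, and interferon-stimulated -0.17, interferon-gamma induced -0.0314 and proliferation -0.21 in Kupffer-like cells, and stress 0.0206 and suppressive -0.12 in monocyte-like cells were the list medians. Ccl8 -0.33 and Spp1 -0.13 in monocyte-like cells, and Nrgn -0.43 in macrophage-like cells, and Ccl5 0.15, Klf2 -0.46, Il2ra -0.0682 and Cxcr3 -0.0241 in CD8 T-like cells, and Zfp420 0.0387 and Rpl39l -0.22 in Kupffer-like cells were the log2 gene ratios.

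With the 30% mitochondrial limit, share ratios were 1.19 (CD8 T-like), 1.22 (macrophage-like), 0.876 (Kupffer-like), 0.831 (Ptprc-low), 1.13 (monocyte-like) and 1.204 (fibroblast-like). Cytotoxic effector -0.12 and proliferation -0.11 in CD8 T-like cells, and MHC class II 0.36, proliferation -0.0955, stress 0.0239, suppressive -0.12 and Kupffer identity -0.0973 in macrophage-like cells, and interferon-stimulated -0.18, interferon-gamma induced -0.0313 and proliferation -0.32 in Kupffer-like cells, and stress 0.001 and suppressive -0.0317 in monocyte-like cells, and interferon-gamma induced 0.69 in fibroblast-like cells, and hepatocyte transcripts -0.22 and hemoglobin 0.55 in Ptprc-low cells were the list medians. Ccl8 -0.34, Zfp930 -0.11 and Spp1 -0.0317 in monocyte-like cells, and Nrgn -0.41 and Stmn1 -0.017 in macrophage-like cells, and Ccl5 0.15 and Il2ra -0.13 in CD8 T-like cells, and Rpl39l -0.19 in Kupffer-like cells, and Ttr -0.16, Hba-a1 0.37 and Hba-a2 0.19 in Ptprc-low cells were the log2 gene ratios. Il7r 0.211 and Top2a -1.98 percentage points were the differences in the share of CD8 T-like cells with a UMI.

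With the first naming rule, share ratios were 1.04 (CD8 T-like) and 1.68 (Ptprc-low). The fibroblast-like class then held 545 vehicle and 605 F5446 cells, many of them Ptprc-low in the main processing. Interferon-stimulated -0.11, interferon-gamma induced 0.0434, MHC class I -0.0749 and proliferation -0.0908 in fibroblast-like cells were the list medians. Inmt 0.0676, Ido1 0.0556 and Zfp455 0.32 in Ptprc-low cells, and Cxcl10 -0.45, Ccnb1 -0.14 and Mki67 -0.23 in fibroblast-like cells were the log2 gene ratios. Il7r 0.721 percentage points was the difference in the share of CD8 T-like cells with a UMI.

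With doublets kept, share ratios were 0.752 (macrophage-like) and 0.593 (Kupffer-like). Interferon-gamma induced -0.022 in Kupffer-like cells was the list median. Socs1 -0.0118 in Kupffer-like cells, and H2-T23 0.0515 in Ptprc-low cells were the log2 gene ratios. Il7r 1.75 percentage points was the difference in the share of CD8 T-like cells with a UMI.

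With no cell filter, share ratios were 1.05 (macrophage-like), 0.870 (Kupffer-like), 0.833 (Ptprc-low), 0.958 (monocyte-like) and 3.87 (fibroblast-like). Cytotoxic effector -0.0296 in CD8 T-like cells, and MHC class II 0.30, H3K9 -0.0108, proliferation -0.26, stress 0.0455 and Kupffer identity -0.0587 in macrophage-like cells, and interferon-stimulated -0.19, interferon-gamma induced -0.0705 and proliferation -0.15 in Kupffer-like cells were the list medians. Rundc3b 0.0884, Gzma 0.17, Ccl5 0.30, Cd244a 0.0198 and Il2ra -0.44 in CD8 T-like cells, and Ccl8 -0.0705, Zfp930 -0.23 and Spp1 -0.0372 in monocyte-like cells, and Nrgn -0.37, Zgrf1 -0.0304, Suv39h1 -0.088 and Stmn1 -0.21 in macrophage-like cells, and Socs1 -0.0399, Rpl39l -0.19 and Fabp1 0.13 in Kupffer-like cells were the log2 gene ratios. Il7r 0.0059 percentage points was the difference in the share of CD8 T-like cells with a UMI.

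With cells thinned to 1000 UMIs, cytotoxic effector -0.32 and stress -0.0161 in CD8 T-like cells, and MHC class II 0.12 in macrophage-like cells, and interferon-stimulated -0.0063 in Kupffer-like cells, and interferon-gamma induced 1.18 in fibroblast-like cells, and interferon-gamma induced -0.26 in Ptprc-low cells were the list medians. Cntln -0.0786, Skic3 -0.37, Fasl 0.51, Klf2 -0.82, Il2ra -0.37, Tasor -0.12 and Ccnb1 -0.0316 in CD8 T-like cells, and Catsperd -0.0137, Ido1 1.21, Mki67 0.41 and Fosb -0.30 in Ptprc-low cells, and Zfp366 -0.0852, Rpl39l 0.19 and Ttr -0.93 in macrophage-like cells, and H2-Eb1 -0.0017 in monocyte-like cells, and Nos2 -0.16, H2-Q7 -0.85 and Zfp521 -0.16 in fibroblast-like cells were the log2 gene ratios.

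At Leiden resolution 0.5, cytotoxic effector -0.11 in CD8 T-like cells was the list median. Gzmd 0.96 and Gzme 0.61 in CD8 T-like cells were the log2 gene ratios. Il7r 1.81 percentage points was the difference in the share of CD8 T-like cells with a UMI.

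With each cell weighted equally, MHC class II 0.13 in macrophage-like cells, and hepatocyte transcripts -0.28 in Ptprc-low cells were the list medians. H2-Eb1 -0.006 in monocyte-like cells, and Ttr -0.0999 in Ptprc-low cells were the log2 gene ratios.

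At Leiden resolution 2.0, MHC class II 0.34 in macrophage-like cells was the list median.

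Without the Alox15 and Prg4 cluster, hemoglobin 0.82 in macrophage-like cells was the list median. Ccl8 -0.0668, Prok2 1.18, Tgfb2 0.89, Selp 0.80, Garnl3 0.46 and Hba-a2 0.80 in macrophage-like cells were the log2 gene ratios. Outside that cluster Prok2 had 0 and 0 UMIs, so its value comes from the prior and the class totals alone, and Tgfb2 had 5 and 4 UMIs.

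With CD8 T-like sub-clusters given the same weights in both libraries, Gzmb 0.0181 in CD8 T-like cells was the log2 gene ratio.

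With cells thinned to 2000 UMIs, Ifng 6.84 and Il7r 0.0144 percentage points were the differences in the share of CD8 T-like cells with a UMI.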

Other observations

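Further classes, not compared at the 10% mitochondrial limit, were compared at the 30% limit after the data had been seen, and no tests were run on them. NK-like cells of the F5446 library had less RNA of cell division genes, with a proliferation median of -0.52 (7 of 19 members at least 1.5-fold lower, 12 between), and of NK maturation genes (-0.47; the chemokine receptor Cx3cr1 -1.68). Their median mitochondrial shares were 12.8% and 18.2%, proliferation medians at this limit were also negative in CD8 T-like (-0.11) and Kupffer-like cells (-0.32), and with 2000 UMIs per cell Mki67 was found in 7.31% and 7.14% of NK-like cells. Their cytotoxic median was -0.09 and Gzmc, a granzyme, was at -1.92 (3331 and 379 UMIs), while Gzmd had 373 and 0 UMIs, at least 53.6-fold lower, from 10 cells. Cd7 was at 0.94 and the sialyltransferase gene St6galnac3 at 1.22. After thinning, Gzmb was found in 57.4% and 47.6% of NK-like cells, Prf1 in 32.0% and 22.4%, Ifng in 7.26% and 3.53%, and Gzma in 79.5% and 82.4%, at median depths of 5065 and 4502 UMIs. Without thinning these were 83.8% and 78.9%, 73.3% and 60.2%, 27.4% and 22.2%, and 87.8% and 86.5%. B-like cells gave a background of 0.543% and 0.475% for Gzmb and 1.24% and 0.238% for Gzma. CD8 T-like cells at this limit had Gzmb in 36.3% and 39.2%, and Prf1 in 21.8% and 18.6%.

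Neutrophil-like cells of the F5446 library at that limit had more RNA of inflammatory genes (0.28; 5 of 15 at least 1.5-fold higher, 10 between) and of suppressive neutrophil genes (0.19; 3 higher, 13 between). The acute phase gene Saa3 was at 2.82 and the chemokine genes Cxcl3 at 2.35 and Ccl3 at 1.28. Proliferation (-0.83; 13 lower, 6 between) and granule genes (-0.46; 2 higher, 5 lower, 5 between; Camp -1.34) were lower, as was Olfm4, a granule protein gene (-2.07). Hemoglobin RNA in this class was at -6.19 and the mitochondrial list at 0.34.

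B-like cells had a lower interferon-stimulated median at that limit (-0.49; 7 of 19 lower, 12 between) and a higher B cell activation median (0.28; 3 higher, 12 between). The secretory genes Xbp1 (1.23) and Sdf2l1 (1.15) were higher too. The plasma cell markers Jchain, Igha and Iglc2 were among the leading genes of the B-like class, and no plasma-like class was named at this limit. Plasma cells may therefore lie within the B-like class, and their part in these values was not tested. Slpi was at 4.67 (234 and 4256 UMIs). Gzmd, with 111 and 0 UMIs, came from 5 vehicle B-like cells. CD4 T-like cells had lower interferon-gamma induced (-0.75; 1 higher, 9 lower, 2 between) and interferon-stimulated genes (-0.57), with Il18r1 at -1.29 and Ifngr1 at -1.16. The dendritic cell maturation list was at 0.22 in cDC1-like cells, with Cd274 (PD-L1) at 1.002, and at 0.36 in mature DC-like cells, with Relb at 0.57. Endothelial-like cells had lower interferon-stimulated genes (-0.34) and higher Slpi (2.47), with hemoglobin RNA at 3.24.

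At the 10% limit, named classes under 100 cells in a library were NK-like (97 and 12 cells), neutrophil-like (111 and 37), immature neutrophil-like (61 and 72), cDC1-like (167 and 97), mature DC-like (111 and 48), regulatory T-like (33 and 8), plasmacytoid DC-like (32 and 4), plasma-like (10 and 18), endothelial-like (120 and 76) and erythroid-like cells (73 and 15). No B-like or CD4 T-like class was named at that limit, since clusters with such markers were set aside as mixed lineage or left unnamed. In the macrophage-like cluster with Alox15 and Prg4, Alox15 had 1413 and 5 UMIs, Slpi 10741 and 290, and Ccl8 658 and 2670.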
